A study of Homo sapiens with 79 samples.

How the data were processed

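RNA of CD4 T cells and of CD8 T cells of HIV-infected donors was measured on Illumina BeadArrays of 48803 probes. The labels place the cells' source in frozen blood mononuclear cells from which each T cell type was purified. Total RNA was isolated with the mirVana kit and biotin-labelled cRNA was made with the Ambion MessageAmp kit, per the labels. The image software was not given in the sources used here. Every array belonged to 1 of 3 groups of disease course: elite or viremic controllers, rapid progressors, and viremic non-progressors. The first group is called controllers in the text.

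The deposited non-normalized tables, 1 for each cell type, gave for every probe and array an intensity in arbitrary fluorescence units and a detection value. In the CD8 table the deposited detection value was a p-value that fell as the intensity rose, with a rank correlation between -0.999 and -0.993 across the probes of an array. In the CD4 table the deposited detection value carried the same heading but was a score that rose with the intensity, with a rank correlation between 0.987 and 0.999. It was read as 1 minus a detection p and was converted before use. The authors also deposited a matrix of log2 values, in which the arrays of a cell type shared 1 distribution, as quantile normalization within a cell type gives. Its median was 6.51 in CD4 arrays and 7.26 in CD8 arrays. By rank correlation across the probes, each of the 41 CD4 and 38 CD8 columns of that matrix best matched its own array in the non-normalized tables. The authors' log2 values served only as an alternative. All value columns were matched to a sample, and 0 were left over.

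The arrays of each cell type were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p and an offset of 16. A probe was kept when its detection p was under 0.05 on at least 5 arrays of the cell type. This left 22596 probes in CD4 arrays and 18745 in CD8 arrays. For comparisons across cell types, all 79 arrays were normalized together. Of the probes, 27578 had 1 gene symbol, 13 had several, and 21212 had no gene name in the annotation used here. Symbols were updated through the Entrez identifier for 27541 probes, and gene positions were read from the RefSeq annotation of GRCh38.p14. The probe with the highest mean intensity stood for each symbol, which gave 12058 genes in CD4 arrays, 10341 in CD8 arrays and 13254 across both. Probes of Y-linked genes and of XIST, 142 in all, were left out.

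Donors were the replicates. Donor codes in the sample titles paired the arrays of both cell types for 38 of the 41 donors, and sex-linked probes disagreed between the cell types for 0 of the 38. The 3 groups of a cell type were compared pairwise in 1 limma fit (lmFit and eBayes), so that they shared 1 estimate of the spread, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences between cell types were tested with limma on the within-donor difference of log2 intensity, CD8 minus CD4. No covariate was used, since the files name neither the BeadChip, a processing date nor a clinical measure. The only sign of batches was the form of the donor code, which was digits alone for every controller and began with letters for 16 rapid progressors and 1 viremic non-progressor in each cell type.

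Each of 21 gene lists was summarised on every array as the mean log2 intensity of its measured members. Shifts of these means between groups were tested by a two-sided exact permutation of the status labels over all splits, adjusted over the 21 lists and 6 comparisons. The lists covered interferon-stimulated genes, antigen processing and class I, T cell activation, inhibitory receptors, cell cycle, cytotoxic effectors, naive and central memory T cells, regulatory T cells, Th17 cells, inflammasome and caspases, HIV restriction and dependency factors, ribosomal proteins and translation factors, oxidative phosphorylation, and immediate early and heat shock genes. Further lists held markers of monocytes, B cells, NK cells, platelets, erythroid cells, neutrophils with plasmacytoid dendritic cells, and of the CD4 and CD8 lineages. Differences of list shifts between cell types were tested by an exact permutation on the within-donor differences, adjusted over the lists and 3 comparisons. Beside the permutation, limma's camera was run with a preset correlation of 0.01 and with an estimated correlation. Correlations between cell types were given as Pearson's r and Spearman's rho with 100000 permutations, or exact ones for the 8 controllers.

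The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the named genes are, for each status comparison, the 6 largest rises and 6 largest falls among called genes, and from each list the 3 measured members with the smallest p where the list was called and 1 otherwise. Between cell types they are CD4, CD8A, CD8B, the 6 largest rises and falls, and for differences of a status effect up to 6 called genes with the smallest p. The text names fewer of these, and says where a gene was chosen after its values were seen. A second list of 18 monocyte genes, a list of 9 plasma cell genes, and the use of the monocyte marker mean and of the number of probes detected as covariates were chosen after the data were seen.

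Alternatives varied the detection filter, the background correction, the normalization, the source of the values, the variance model, array weights, the groups in the fit, the use of every probe, the handling of the donor code form, the pairing of donors, the list test, and the replicates of the smallest group. For list shifts against controllers, digit codes alone and the code form as a covariate compare the same donors. For viremic non-progressors the omission of replicate 5 compares those donors too. Counts of alternatives include these repeats. The fits were tested on simulated data with the same group sizes and 200 changed genes, all genes being drawn independently of one another. The shares recovered therefore do not carry over to comparisons with fewer, correlated or more variable changed genes. With a simulated log2 change of 1, the share of changed genes recovered ranged from 68.7% to 94.0% over the status comparisons and their differences between cell types. The exact permutation counts equalled full enumeration in 20 of 20 checked cases, and 20 of 400 simulated comparisons without a difference gave p under 0.05. Both groups of those comparisons had the same simulated spread, so they do not show how the test behaves when spreads differ. Where the smaller group is spread more widely, its p also reflects that spread. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the permutations and plots.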

Results

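Gene expression was measured in purified CD4 T cells on 41 arrays and in purified CD8 T cells on 38 arrays, from 41 HIV-infected donors whose infection had taken different courses. The CD4 arrays came from 9 controllers (elite and viremic controllers under 1 label), who hold the virus at low levels without treatment, 27 rapid progressors, and 5 viremic non-progressors, who keep a stable course despite circulating virus. The CD8 arrays came from 8 controllers, 25 rapid progressors and 5 viremic non-progressors, and all 38 of these donors also had a CD4 array. The series asks which genes go with the distinct courses of disease. Median probe intensity per array ranged from 76.8 to 125.1 in CD4 cells and from 95.25 to 177.9 in CD8 cells. Between 9685 and 17344 probes per array were detected in CD4 cells, and between 9795 and 16046 in CD8 cells. The groups differed in CD8 cells, at 11343 ± 973 (mean ± SD) in controllers, 12500 ± 1000 in rapid progressors and 13115 ± 2325 in viremic non-progressors. In CD4 cells the same groups had 13434 ± 2252, 14276 ± 2051 and 13463 ± 1056. The number of arrays, smallest for the viremic non-progressors, limits the precision of every comparison. Values are log2 intensities, given as mean ± SD, and differences of log2 intensity are given ± SE from limma.

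The comparison of rapid progressors with controllers in CD4 T cells asks what separates fast disease from natural control, and its called genes were mostly interferon-stimulated. IFI44L, a gene that interferon switches on strongly, rose from 6.29 ± 1.04 in 9 controllers to 9.53 ± 0.98 in 27 rapid progressors. That difference was 3.24 ± 0.34 log2 units, or 9.43-fold (limma adjusted p = 6.10e-08), and 26 of 27 rapid progressors lay above all controllers. IFI27, a mitochondrial interferon response gene, was 10.4-fold higher, by 3.37 ± 0.72 (limma adjusted p = 0.0214), and 23 of 27 rapid progressors lay above all controllers. The antiviral GTPase gene MX1 was 3.96-fold higher, by 1.98 ± 0.27 (limma adjusted p = 1.93e-05), with 25 of 27 above all controllers. IFI44 rose by 2.06 ± 0.27, EPSTI1 by 1.75 ± 0.30 and the viral entry inhibitor IFITM3 by 2.15 ± 0.44, with limma adjusted p of 1.08e-05, 0.00108 and 0.0154. For these 3 genes 22, 23 and 11 of 27 rapid progressors lay above all controllers. IFI44L and IFI44 are neighbours on chromosome 1 (78620448 to 78646145 and 78649789 to 78664078), while IFI27 lies on chromosome 14 and MX1 on chromosome 21. In all, 22 of 12058 genes were called, all of them higher in rapid progressors. Of these, 17 belonged to the interferon list, and the other 5, chosen for naming after their values were seen, were TYMP, LGALS9, HELZ2, CENPN and SYNCRIP, at 1.12, 1.09, 1.08, 0.71 and 0.53.

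As a group, the interferon-stimulated genes were 0.87 log2 units (1.83-fold) higher in the rapid progressors' CD4 cells, at 7.59 ± 0.49 against 6.72 ± 0.22 (exact permutation adjusted p = 6.58e-04). Of 27 rapid progressors, 24 lay above all 9 controllers. Of the 60 measured genes of the list 57 were higher, 17 were called among all genes, and 43 were higher and 1 lower when adjusted over the list alone. The cell cycle list rose by 0.35 (exact permutation adjusted p = 0.0248, or 0.155 by camera with an estimated correlation), from 0.13 to 0.45 over 10 alternatives of which 7 passed, and 18 of 27 rapid progressors lay above all controllers. All 25 measured cell cycle genes were higher, 13 of them past the threshold adjusted over the list alone and 0 among all genes. TYMS, which makes thymidylate for DNA, was higher by 0.97 ± 0.25 (limma adjusted p = 0.108), and the spindle gene NUSAP1 by 0.79 ± 0.20 (limma adjusted p = 0.0966). The list of HIV restriction and dependency factors rose by 0.25 (exact permutation adjusted p = 0.0122, or 0.537 by camera with an estimated correlation), from 0.17 to 0.27 over 10 alternatives of which 7 passed (adjusted p up to 0.161), with 17 of 27 rapid progressors above all controllers. Adjusted over the list alone 3 of its 19 genes were higher, against 1 among all genes, and the cytidine deaminase APOBEC3A was higher by 1.69 ± 0.42 (limma adjusted p = 0.0867). Without the 4 members it shares with the interferon list, the shift was 0.09 (exact p = 0.0734).

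Other groups of genes did not pass in the CD4 cells of rapid progressors against controllers. Antigen processing and class I was higher by 0.16 (exact permutation adjusted p = 0.0847, 23 of 27 above the controllers' median), with 5 of 18 genes higher adjusted over the list alone and 0 among all genes. Erythroid markers were lower, at -0.36 (exact permutation adjusted p = 0.0898), and monocyte markers were higher by 0.46 (exact permutation adjusted p = 0.337). T cell activation markers differed by 0.21, cytotoxic effectors by -0.26, naive and central memory genes by -0.12, Th17 genes by -0.02, inhibitory receptors by 0.02 with a median gene at -0.07, and regulatory T cell genes by 0.03 with a median gene at -0.04. The lists of inflammasome and caspases, ribosomal and translation genes, oxidative phosphorylation, and immediate early and heat shock genes differed by 0.12, -0.10, 0.07 and 0.01. Markers of B cells, NK cells, platelets, neutrophils with plasmacytoid dendritic cells, and of the CD4 and CD8 lineages differed by 0.13, -0.02, 0.08, 0.06 and -0.01. Among the donors whose code was digits alone, 11 rapid progressors and 9 controllers, the interferon shift was 0.87 (exact p = 0.00122), the cell cycle shift 0.30 (exact permutation adjusted p = 0.156), and 2 genes were called. No controller had the other form of code.

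Viremic non-progressors and controllers share a stable course, and their CD4 cells differed in the interferon-stimulated genes too. IFI44L was 10.2-fold higher, by 3.34 ± 0.50 (limma adjusted p = 3.99e-04), and IFI44 was 3.96-fold higher, by 1.99 ± 0.39 (limma adjusted p = 0.04999). For both genes all 5 viremic non-progressors lay above all 9 controllers, and these were the 2 called genes. Without any 1 viremic non-progressor IFI44 missed the threshold, with limma adjusted p of 0.168, 0.205, 0.163, 0.162 and 0.0790 without replicates 1 to 5. In donors with codes of digits alone IFI44L and IFI44 both missed it, at 3.37 and 2.03 (limma adjusted p = 0.102 and 0.426). These are the donors left without replicate 5, where IFI44L was called at the same 3.37 (limma adjusted p = 0.00247). The fit with digit codes alone has fewer rapid progressors behind its estimate of the spread, so this miss does not show a dependence on the code. IFITM3 was 6.13-fold higher, by 2.62 ± 0.64, without being called (limma adjusted p = 0.242). The interferon list rose by 0.89, to 7.61 ± 0.21 (exact permutation adjusted p = 0.0122), with 5 of 5 above all controllers, 27 of 60 genes higher adjusted over the list alone and 2 among all genes. Antigen processing and class I rose by 0.32 (exact permutation adjusted p = 0.0484, and 0.0407 to 0.118 over 15 alternatives of which 4 passed), with 4 of 5 above all controllers, 17 of 18 genes higher, 1 of them past the threshold adjusted over the list alone and 0 among all genes. Its proteasome activator gene PSME2 was higher by 0.75 ± 0.22 (limma adjusted p = 0.502). The cell cycle list rose by 0.29 (exact permutation adjusted p = 0.0315) and the restriction factor list by 0.31 (exact permutation adjusted p = 0.0157), each with 4 of 5 above all controllers, and both had p = 0.411 by camera with an estimated correlation. Over 15 alternatives these shifts ranged from 0.10 to 0.37 and from 0.20 to 0.35, and 4 and 11 of the alternatives passed. Adjusted over the list alone 0 of 25 cell cycle genes and 2 of 19 restriction factor genes were higher, against 0 and 0 among all genes. Without the genes shared with the interferon list the restriction factor shift was 0.12 (exact p = 0.181). With 5 viremic non-progressors, a simulated log2 change of 1 was recovered in 74.6% of genes and one of 0.5 in 14.9%.

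The comparison of rapid progressors with viremic non-progressors in CD4 cells, groups that differ in outcome, gave 0 called genes in limma, with 477 at an unadjusted p under 0.05 where chance would give 603. The interferon list differed by -0.03 (exact permutation adjusted p = 0.992), from 7.59 ± 0.49 in rapid progressors to 7.61 ± 0.21 in viremic non-progressors. The RNA sensor IFIH1 was the list's gene with the smallest p and was higher in rapid progressors by 0.84 ± 0.29 (limma adjusted p = 0.998). The ribosomal gene RPL7A was lower at -0.75 ± 0.22 and FHIT, a gene of naive cells, at -0.82 ± 0.32, with the same limma adjusted p of 0.998. Among the lists, antigen processing and class I came nearest, at -0.16 (exact permutation adjusted p = 0.171), and cytotoxic effectors were lower at -0.46 (exact permutation adjusted p = 0.487). Simulated changes of 1 log2 unit were recovered in 86.6% of genes at these group sizes and changes of 0.5 in 37.3%. Those shares hold for the simulated genes and do not carry over to the real ones, so changes of either size were not excluded.

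**Figure D1:**
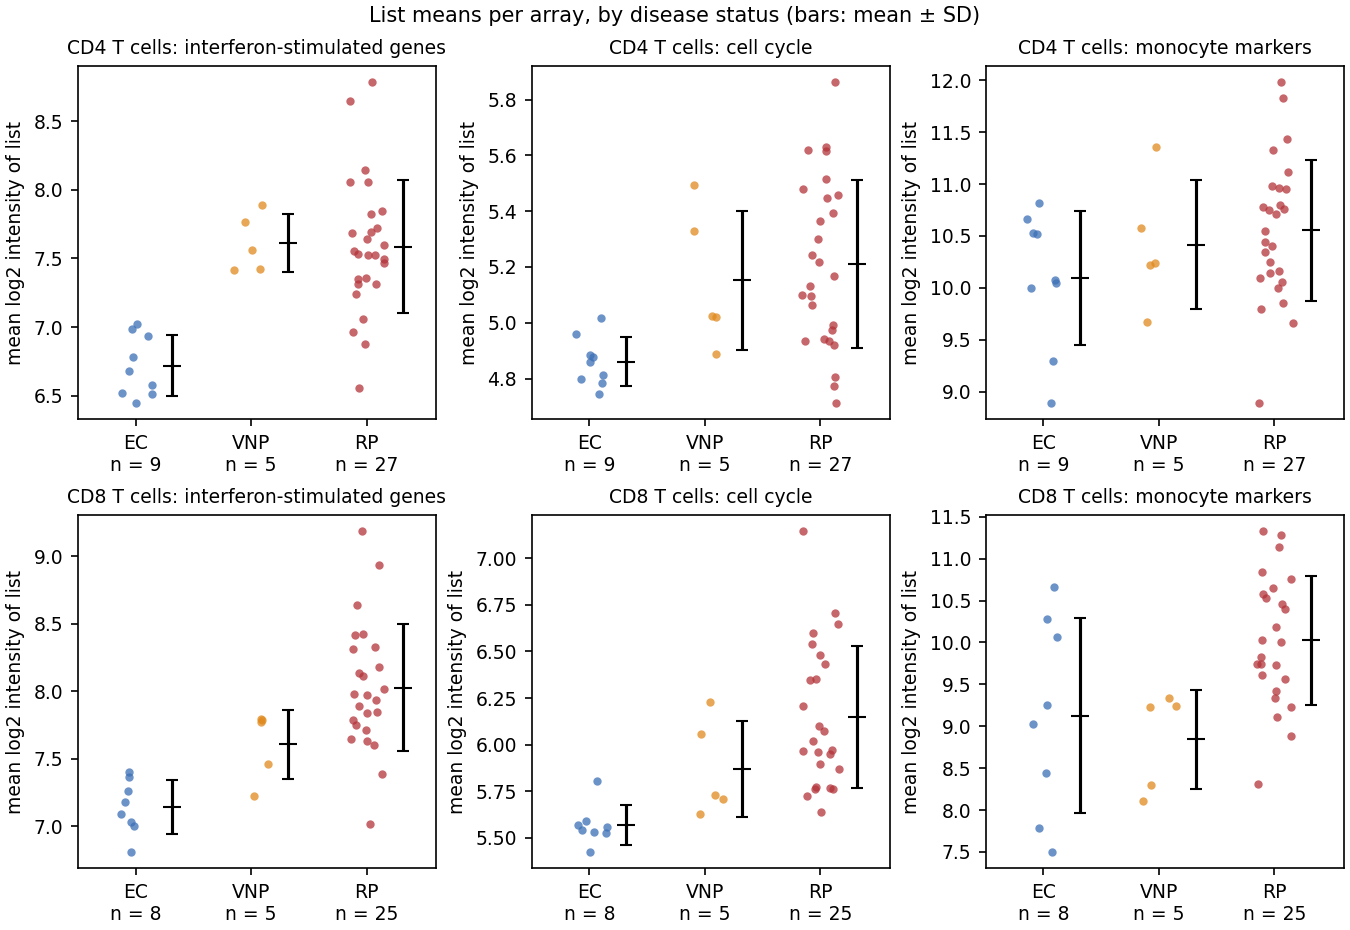
Mean log2 intensity per array of the interferon-stimulated, cell cycle and monocyte marker lists (y axis) in controllers, rapid progressors and viremic non-progressors (x axis), in CD4 cells (top) and CD8 cells (bottom), with bars for mean ± SD. In CD4 cells the interferon list averaged 6.72 in controllers against 7.59 and 7.61 in the other groups, and in CD8 cells the monocyte list averaged 10.03 in rapid progressors and 8.85 in viremic non-progressors.

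In CD8 T cells, where antiviral killing resides, rapid progressors differed from controllers in interferon-stimulated and cell cycle genes. IFI44L was 9.53-fold higher, by 3.25 ± 0.44 (limma adjusted p = 4.77e-05), with 23 of 25 rapid progressors above all 8 controllers. MX1 was 4.19-fold higher, by 2.07 ± 0.30 (limma adjusted p = 1.10e-04), with 23 of 25 above all controllers. TYMS was 3.49-fold higher, by 1.80 ± 0.32 (limma adjusted p = 0.00171), at 6.64 ± 0.97 against 4.84 ± 0.20, with 23 of 25 above all controllers. The replication helicase gene MCM5 was higher by 0.90 ± 0.15 (limma adjusted p = 5.66e-04), with 22 of 25 above all controllers, and GINS2, of the same helicase complex, by 1.44 ± 0.27 (limma adjusted p = 0.00235), with 23 of 25. IFI27, IFITM3, IFI44 and EPSTI1 rose by 2.98 ± 0.70, 2.19 ± 0.45, 2.03 ± 0.32 and 1.92 ± 0.28, with limma adjusted p of 0.0197, 0.00662, 3.53e-04 and 1.11e-04. The surrogate light chain gene IGLL1, of the B lineage, was 6.13-fold higher, by 2.62 ± 0.52 (limma adjusted p = 0.00382), with 18 of 25 above all controllers. Limma called 156 of 10341 genes, 123 higher and 33 lower in rapid progressors, of which 36 were in a list and 87 higher and 33 lower were in none. Those counts depended on the processing, at 34 higher and 1 lower with cyclic loess, 21 and 2 with the code form as a covariate, 34 and 2 with the number of probes detected as a covariate, and 63 and 8 with array weights. In donors with codes of digits alone they were 9 and 1, and with the monocyte marker mean as a covariate 211 and 97.

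The 6 largest falls among the 33 lower genes, whose number depended on the processing, lay between -0.81 and -0.69. The stress transcription factor DDIT3 was lower at -0.81 ± 0.21 and the chaperone HSPA5 at -0.70 ± 0.18, with limma adjusted p of 0.0388 and 0.0325. HSPB1, another chaperone gene, was at -0.73 ± 0.20, with 24 of 25 rapid progressors below the controllers' median and 2 below all controllers (limma adjusted p = 0.0475). The zinc finger gene ZNF329 was at -0.75 ± 0.18, with 21 of 25 below all controllers (limma adjusted p = 0.0199). FSHR and EPHA8, a hormone receptor and an ephrin receptor, were at -0.75 ± 0.14 and -0.69 ± 0.19, with limma adjusted p of 0.00227 and 0.0482. The immediate early and heat shock list, which held 0 of the 33 lower genes, differed by -0.11 (exact permutation adjusted p = 0.856), with 6 of 25 above the controllers' median.

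The interferon list of the CD8 cells was 0.88 higher, at 8.03 ± 0.47 in rapid progressors against 7.14 ± 0.20 in controllers (exact permutation adjusted p = 6.58e-04). By camera with an estimated correlation its adjusted p was 0.0649. Of 25 rapid progressors 23 lay above all controllers, and 43 of 55 genes were higher adjusted over the list alone, 24 among all genes. The cell cycle list rose by 0.58 (exact permutation adjusted p = 0.0105, or 0.218 by camera with an estimated correlation) and by 0.22 to 0.71 over 10 alternatives, which all passed, with 19 of 25 above all controllers, 17 of 24 genes higher adjusted over the list alone and 8 among all genes. A plasma cell list, chosen after the data were seen, was higher beside it by 0.53 (exact p = 8.53e-04). T cell activation markers rose by 0.32 (exact permutation adjusted p = 0.0375, or 0.411 by camera with an estimated correlation), with 18 of 25 above all controllers, 2 of 14 genes higher adjusted over the list alone and 0 among all genes. Of 10 alternatives 5 passed for that list, and with the monocyte marker mean as a covariate its shift was 0.17 (exact permutation adjusted p = 0.294, the highest of the 10, where the lowest was 0.0333). CD38, a surface enzyme of activated T cells and of plasma cells, was higher by 0.85 ± 0.24 and HLA-DMB, which monocytes also express, by 0.67 ± 0.22 (limma adjusted p = 0.0633 and 0.102). The regulatory T cell list rose by 0.29 (exact permutation adjusted p = 0.0122, or 0.411 by camera with an estimated correlation), from 0.12 to 0.42 over 10 alternatives of which 8 passed (adjusted p up to 0.120), with 12 of 25 above all controllers, 2 of 7 genes higher adjusted over the list alone and 0 among all genes. The checkpoint receptor CTLA4 in that list was higher by 0.94 ± 0.30 (limma adjusted p = 0.0903). HIV restriction and dependency factors rose by 0.30 (exact permutation adjusted p = 0.00450, or 0.437 by camera with an estimated correlation), from 0.17 to 0.32 over 10 alternatives of which 8 passed (adjusted p up to 0.0829), with 20 of 25 above all controllers, 4 of 18 genes higher adjusted over the list alone and 2 among all genes, IFITM3 and APOBEC3A. Without the 4 genes shared with the interferon list that shift was 0.13 (exact p = 0.0456).

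Several groups of genes missed the threshold in CD8 cells of rapid progressors against controllers. Antigen processing and class I was higher by 0.22 (exact permutation adjusted p = 0.0851), although its gene PSME2 was called at 0.79 ± 0.14 (limma adjusted p = 0.00171), and 6 of 17 genes were higher adjusted over the list alone against 1 among all genes. Monocyte markers were higher by 0.90 (exact permutation adjusted p = 0.104, 22 of 25 above the controllers' median), with 10 of 15 genes higher adjusted over the list alone and 1 among all genes, the protease gene CTSS at 0.76 ± 0.21. Inhibitory receptors were higher by 0.25 and B cell markers by 0.32 (exact permutation adjusted p = 0.115 and 0.203). NK cell markers and cytotoxic effectors differed by -0.01 and 0.09 (exact permutation adjusted p = 0.992 and 0.966). In donors with codes of digits alone, 9 rapid progressors against 8 controllers, the interferon shift was 0.96 (exact p = 0.00148), the cell cycle shift 0.50 (exact permutation adjusted p = 0.0467), and limma called 10 genes. Of the 9145 genes tested in both cell types, 15 were called higher in rapid progressors than controllers in both, 13 of them in the interferon list. Independent calls would share 0.296, but the cell types share donors, so these calls are not independent. With the 38 shared donors alone 8 genes were called in both, against at most 0 when the donors were relabelled in both cell types at once.

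**Figure D2:**
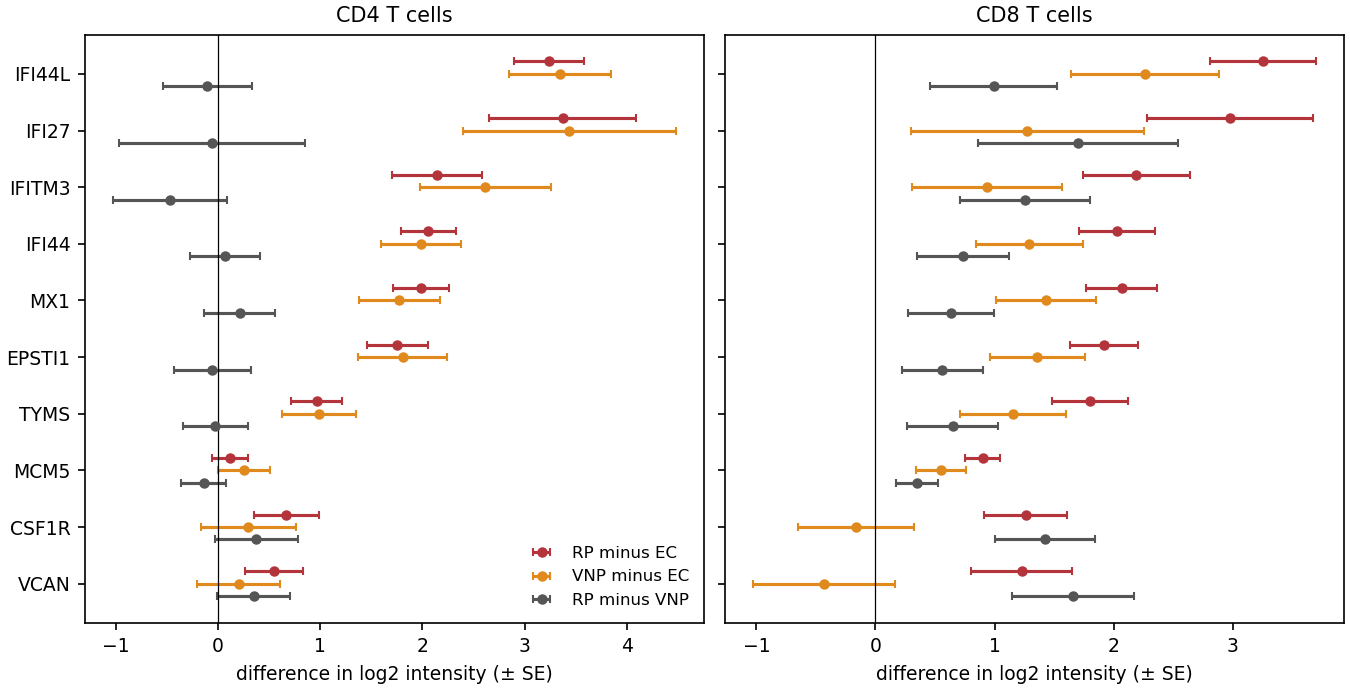
Differences of log2 intensity ± SE (x axis) of 10 genes between the status groups, rapid progressors minus controllers, viremic non-progressors minus controllers and rapid progressors minus viremic non-progressors, in CD4 and CD8 cells. IFI44L differed from controllers by 3.24 in CD4 cells and 3.25 in CD8 cells of rapid progressors, and by 3.34 and 2.26 in those of viremic non-progressors.

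Viremic non-progressors and controllers gave 0 called genes in CD8 cells by limma, with 673 at an unadjusted p under 0.05 where chance would give 517. IFI44L was higher by 2.26 ± 0.62, MX1 by 1.43 ± 0.42 and CTLA4 by 1.51 ± 0.42, each with a limma adjusted p of 0.661. The interferon list rose by 0.46, to 7.61 ± 0.26 from 7.14 ± 0.20 (exact permutation adjusted p = 0.0490, or 0.411 by camera with an estimated correlation), with 4 of 5 viremic non-progressors above all 8 controllers. Adjusted over the list alone 3 of 55 genes were higher, against 0 among all genes. Of 15 alternatives 7 passed for that shift, which was 0.42 in donors with codes of digits alone (exact permutation adjusted p = 0.112). The same donors were compared with the code form as a covariate and without replicate 5, so these are not separate checks. The shift missed the threshold without replicate 1, 2, 3 or 5, at 0.42, 0.50, 0.42 and 0.42 (exact permutation adjusted p = 0.101, 0.0727, 0.101 and 0.0849). With 1 donor fewer there are fewer splits, which by itself raises the smallest p that can be reached. The cell cycle list was higher by 0.30 (exact permutation adjusted p = 0.0718) with all 5 above the controllers' median, and monocyte markers differed by -0.28 (exact permutation adjusted p = 0.966). A simulated log2 change of 1 was recovered in 68.7% of genes at these group sizes.

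Rapid progressors and viremic non-progressors differed in the monocyte markers of the CD8 fraction, which were 1.18 higher (2.27-fold), at 10.03 ± 0.77 in 25 rapid progressors against 8.85 ± 0.59 in 5 viremic non-progressors (exact permutation adjusted p = 0.0327, or 0.155 by camera with an estimated correlation). Of the rapid progressors 20 lay above all viremic non-progressors, and all 15 measured genes were higher when adjusted over the list alone, against 0 among all genes. The growth factor receptor CSF1R was 2.69-fold higher, by 1.43 ± 0.42, the matrix gene VCAN by 1.66 ± 0.51 and the monocyte membrane gene MS4A7 by 1.06 ± 0.32, each with a limma adjusted p of 0.699. Among donors with codes of digits alone the shift was 1.44 (exact permutation adjusted p = 0.103). Without viremic non-progressor replicate 3 the shift was 0.998 (exact permutation adjusted p = 0.127) and without replicate 4 it was 1.05 (exact permutation adjusted p = 0.0972). Neutrophil and plasmacytoid dendritic cell markers were higher by 0.37 (exact permutation adjusted p = 0.104), B cell, platelet and erythroid markers differed by 0.14, 0.04 and 0.01, and NK cell markers by 0.00 with a median gene at -0.14. The interferon list was higher by 0.42 (exact permutation adjusted p = 0.271), T cell activation markers by 0.28 (exact permutation adjusted p = 0.204) and the HLA class II gene HLA-DMB by 0.88 ± 0.27 (limma adjusted p = 0.699). Limma called 0 of 10341 genes, with 613 at an unadjusted p under 0.05 where chance would give 517.

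Camera with an estimated correlation passed for 3 list shifts. These were the interferon list in CD4 cells against controllers, in rapid progressors (adjusted p = 0.0122) and in viremic non-progressors (adjusted p = 0.0203), and antigen processing and class I in CD4 cells of viremic non-progressors against controllers (adjusted p = 0.0203).

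Within the 38 donors with both cell types, CD8A was 5.85 ± 0.13 and CD8B 3.40 ± 0.10 higher in CD8 arrays, in 38 of 38 donors each, and CD4 differed by -1.01 ± 0.10, being lower in CD8 arrays of 36 of 38 donors. The cytotoxic cell genes KLRD1, GZMH and NKG7 were higher in CD8 arrays by 4.17, 3.87 and 3.74, and the costimulatory receptor TNFRSF4 was lower at -2.59, all past the limma threshold. In the authors' log2 values, whose median was higher in CD8 arrays (7.26 against 6.51), CD4 stood 0.31 higher in CD8 arrays. Limma called 9575 of 13254 genes, 4371 higher and 5204 lower in CD8 arrays, and since each cell type came as its own array table, cell type and table could not be told apart. The balance of rises and falls rests on the joint normalization: with each cell type normalized on its own 10280 genes were higher and 731 lower, and in the authors' values 12928 were higher and 132 lower.

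The interferon list means of both cell types were correlated across donors, and within rapid progressors and within controllers. Across the 38 donors, the interferon list means of CD4 and CD8 cells correlated with Pearson r = 0.93 and Spearman rho = 0.89 (permutation p = 1e-05 for both, the smallest the permutations can give, and adjusted p = 1.5e-05 over the 3 donor sets tested). Since the status groups differ in level, the values within groups are the main ones. Within the 25 rapid progressors r was 0.98 and rho 0.97 (permutation p = 1e-05, adjusted p = 1.5e-05), and without the 2 donors farthest from the median r was 0.96. Within the 8 controllers r was 0.86 and rho 0.83 (exact p = 0.00759 and 0.0154, unchanged by the adjustment). Without the 2 farthest controllers r was 0.70 (exact p = 0.108), and it was 0.86 without background correction and 0.84 in the authors' values (exact p = 0.0347 and 0.0431). Within the 5 viremic non-progressors, a group added after the values were seen, r was -0.05 and rho 0.40 (exact p = 0.933 and 0.517).

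**Figure D3:**
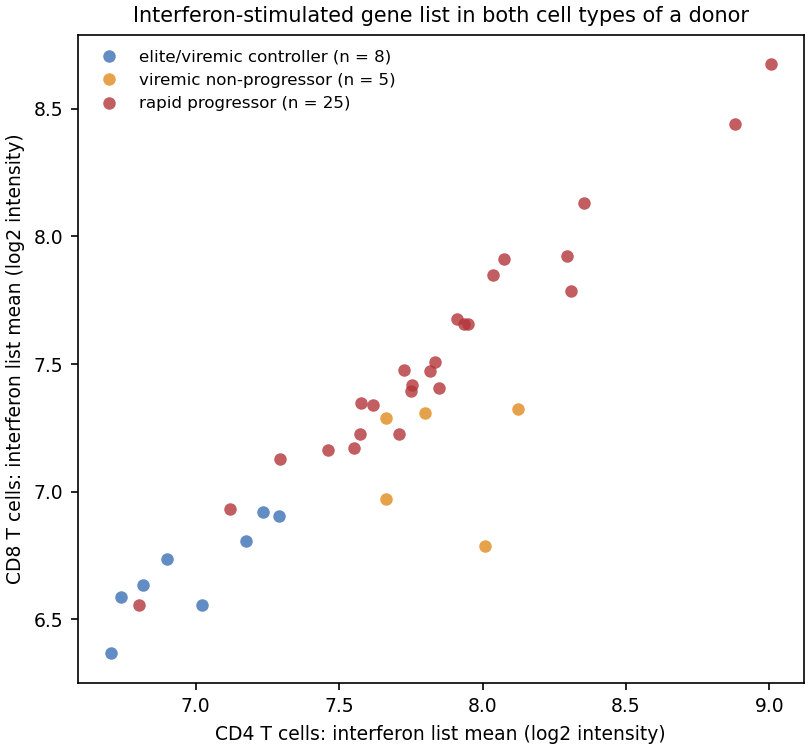
Mean log2 intensity of the interferon-stimulated list in CD4 cells (x axis) and CD8 cells (y axis) of the 38 donors with both cell types, 1 point per donor, coloured by status. Pearson r was 0.98 within the 25 rapid progressors, and the mean within-donor difference of CD8 minus CD4 cells was lowest in viremic non-progressors, at -0.72, although the points of the groups overlap.

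The effect of status on interferon-stimulated genes differed between the cell types where viremic non-progressors were involved. Their CD8 minus CD4 difference of the interferon list was -0.72 ± 0.33 (SD, n = 5), against -0.31 ± 0.10 in rapid progressors (n = 25) and -0.30 ± 0.12 in controllers (n = 8). Rapid progressors minus viremic non-progressors was thus 0.41 larger in CD8 than in CD4 cells (exact permutation adjusted p = 0.00796), and viremic non-progressors minus controllers was 0.42 smaller in CD8 cells, at -0.42 (exact permutation adjusted p = 0.0490). The smallest group had the widest spread, and an exact permutation of labels also responds to unequal spread. Both p-values therefore do not measure the difference of means alone. Without any 1 viremic non-progressor the differences ranged from 0.28 to 0.49 and from -0.50 to -0.29, and the latter missed the threshold without replicate 1, 2, 3 or 4 (exact permutation adjusted p = 0.127, 0.0955, 0.127 and 0.127). With 1 donor fewer there are fewer splits, which by itself raises the smallest p that can be reached. Without replicate 2 or 3 the latter difference was no smaller than over all donors, at -0.43 and -0.48. In donors with codes of digits alone the differences were 0.53 and -0.50 (exact permutation adjusted p = 0.0424 for both), the second over the same donors as without replicate 5. For rapid progressors minus controllers the difference was -0.01 (exact permutation adjusted p = 0.962). The restriction factor list differed for rapid progressors minus viremic non-progressors by 0.17 (exact permutation adjusted p = 0.0210, but 0.127, 0.0610 and 0.127 without replicate 1, 2 or 4). Without the 4 members it shares with the interferon list it was 0.05 (exact p = 0.475), and with all members it was 0.10 without background correction and 0.09 in the authors' values (exact permutation adjusted p = 0.104 and 0.156). The monocyte list differed by 1.03 without passing (exact permutation adjusted p = 0.120). Among single genes, IFI27 differed by 1.80 ± 0.29 for rapid progressors minus viremic non-progressors (limma adjusted p = 0.00269) and by -2.06 ± 0.34 for viremic non-progressors minus controllers (limma adjusted p = 0.00377). Without replicate 2 or 4 both missed the threshold, at 1.55 and 1.52 (limma adjusted p = 0.141 and 0.167) and at -1.81 and -1.78 (limma adjusted p = 0.0919 and 0.103). Without background correction and in the authors' values the first was 1.10 and 1.03 (limma adjusted p = 0.0937 and 0.151). With each cell type normalized on its own, IFI27 in viremic non-progressors was at 8.36 ± 1.10 in CD4 cells and 6.54 ± 0.36 in CD8 cells. In rapid progressors it was at 8.30 ± 2.32 and 8.24 ± 2.22. These levels are not on the joint scale of the tests, so they cannot be subtracted across cell types. FLOT1, a membrane raft gene, differed by -1.50 ± 0.29 for viremic non-progressors minus controllers (limma adjusted p = 0.0331, but 0.196, 0.0565 and 0.317 without replicate 2, 3 or 4), and FSHR by -0.86 ± 0.16 for rapid progressors minus controllers (limma adjusted p = 0.0272). FSHR did not pass the detection filter in CD4 cells, where it averaged 4.59 over all donors, so its difference rests on its CD8 values. FSHR differed by -0.29 without background correction, -0.24 in the authors' values and -0.93 in donors with codes of digits alone (limma adjusted p = 0.174, 0.145 and 0.214), and FLOT1 missed the threshold in those 3 settings too, at -0.81, -0.77 and -1.59 (limma adjusted p = 0.0540, 0.0796 and 0.174). For FLOT1 the same donors were compared without replicate 5, where it was called at the same -1.59 (limma adjusted p = 0.0326). Limma called 1, 1 and 2 of 13254 genes in these 3 tests of a difference.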

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

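Of the tests in this part, the difference between monocyte and B cell markers was chosen only after its result was seen, and the covariates and the second monocyte list were chosen after the data had been looked at.

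The interferon-stimulated list was higher than in controllers by 0.8681 and 0.8844 in CD4 and CD8 cells of rapid progressors and by 0.8935 in CD4 cells of viremic non-progressors. The amount of monocyte RNA as the whole cause was argued against by the shifts with the monocyte marker mean as a covariate, which were 0.7581, 0.7904 and 0.817 (exact p = 2.73e-05, 4.75e-05 and 5.00e-04). That covariate follows only the amount of monocyte RNA. The interferon response of monocytes in the fractions could therefore not be told apart from that of the T cells. Array quality was argued against by the shifts with the number of probes detected as a covariate, at 0.8709, 0.8318 and 0.8936 (exact p = 6.62e-06, 3.06e-05 and 5.00e-04), and the form of the donor code by the shifts among donors with codes of digits alone, at 0.8669, 0.9646 and 0.9422 (exact p = 0.00122, 0.00148 and 0.00140). A batch by BeadChip or date, which the files do not name, stays open. The status of the donors may be the cause and was not tested apart from such a batch, and virus levels were not used here.

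Monocyte markers were 1.183 higher in the CD8 fraction of rapid progressors than of viremic non-progressors, and array quality as the whole cause was argued against by a shift of 1.099 with the number of probes detected as a covariate (exact p = 0.00404). The monocyte list minus CD79A and CD79B, the B cell markers above the median level of all genes, differed by 1.021 (exact p = 0.0164) while those markers rose by 0.162. Chosen after its result was seen and resting on 2 B cell genes, that test cannot decide about fewer CD8 T cells with more of every other cell type. Monocytes left in the purified CD8 cells may be the source, since a second list of 18 monocyte genes, 12 of them measured, was shifted by 0.8611 (exact p = 0.00881). The abundant monocyte genes S100A9, LYZ and CD14, named here outside the rule for naming genes, stood at 12.93, 11.77 and 11.62 in rapid progressors and at 11.59, 10.82 and 10.06 in viremic non-progressors. Of the first list, 2 measured genes, TYROBP and FCER1G, are also in the NK cell list. The purification of CD8 cells should remove monocytes, and whether their number differs with the course of disease or with the handling of the sample cannot be read from these arrays.

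The effect of status on the interferon-stimulated list differed between CD8 and CD4 cells by a test of the difference, by 0.4069 for rapid progressors minus viremic non-progressors and by -0.4197 for viremic non-progressors minus controllers. That test also responds to the wider spread of the viremic non-progressors (SD 0.33, against 0.10 and 0.12 in rapid progressors and controllers). The amount of monocyte RNA and array quality as the whole cause were argued against by the same differences with the within-donor change of the monocyte markers as a covariate, at 0.3722 and -0.3997 (exact p = 2.46e-04 and 0.00233), and with that of the number of probes detected, at 0.424 and -0.4409 (exact p = 9.82e-05 and 0.00233). Here too the interferon response of the monocytes themselves could not be told apart from that of the T cells. A single donor as the cause was argued against by the smallest values without 1 viremic non-progressor, 0.2811 and -0.2939, both without replicate 4 (exact p = 7.58e-04 and 0.00606, the largest over the 5 omissions), although the adjusted p of the second passed the threshold only without replicate 5. A weaker interferon response of CD8 cells in viremic non-progressors may be the cause and stays a hypothesis, as does a batch of their arrays that the files do not name.

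By the same kind of test, the effect of status differed between the cell types in these further results. The HIV restriction and dependency list differed by 0.1733 for rapid progressors minus viremic non-progressors, but by 0.05 without the 4 members it shares with the interferon list (exact p = 0.475), so most of it repeats the interferon result, and by 0.10 without background correction and 0.09 in the authors' values, neither past the threshold. IFI27 differed by 1.795 for that contrast and by -2.055 for viremic non-progressors minus controllers, FLOT1 by -1.503 for the latter, and FSHR by -0.8614 for rapid progressors minus controllers. IFI27 missed the threshold without replicate 2 or 4, and FLOT1 without replicate 2, 3 or 4. FSHR, which did not pass the detection filter in CD4 cells, missed it at -0.29 without background correction and at -0.24 in the authors' values.

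In 5 of 136 groups of arrays tested, 1 array lay far from the others of its group, measured as its gap to the nearest array over the range of the group. The tests covered list means and called genes in the groups of 5 to 9 arrays, and chance alone would give 6.8, or 1 in 20. The ratio was 0.5741 for the highest platelet marker mean in CD4 cells of controllers and 0.7933 for the highest NK cell marker mean in CD4 cells of viremic non-progressors. It was 0.5615 for the highest cell cycle mean in CD8 cells of controllers, 0.7594 for the lowest platelet marker mean in CD8 cells of viremic non-progressors, and 0.8017 for the lowest MX1 value in the latter.

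Counts of called genes were compared with those from 100 splits of the same arrays or donors, the real split included. For rapid progressors against controllers chance was made less likely, since 1 of 100 splits gave as many as the 22 genes of CD4 cells (highest other 1) and 2 of 100 as many as the 156 of CD8 cells (highest other 205). It was not excluded, since 100 splits cannot show a share under 1 of 100 and another split called more CD8 genes than the real one. Chance was likewise made less likely for CD8 against CD4 arrays, where 1 of 100 reversals of cell type within donors gave as many as 9575 genes (highest other 3703). For viremic non-progressors against controllers in CD4 cells chance was not excluded, since 6 of 100 splits gave as many as 2 genes (highest other 10). The comparisons with 0 called genes were matched by 100 of 100 splits each, with highest other counts of 31 and 10 for rapid progressors against viremic non-progressors in CD4 and CD8 cells and 57 for viremic non-progressors against controllers in CD8 cells. In these 3 comparisons 16, 9 and 17 of the 100 splits called any gene, and whether a structure of the samples gave such counts was not tested. For differences of a status effect between cell types chance was not excluded either: 6 of 100 splits gave as many as 1 gene for rapid progressors minus viremic non-progressors (highest other 4), 6 as many as 1 for rapid progressors minus controllers (highest other 2), and 12 as many as 2 for viremic non-progressors minus controllers (highest other 17). With the 38 shared donors relabelled in both cell types at once, the 8 genes called in both for rapid progressors against controllers exceeded all of the other splits (highest 0).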

How the results depend on the processing

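The covariates for monocyte markers and for probes detected were chosen after the data were seen, and the other alternatives before. BeadChip as a random block was not run, since the files name no BeadChip. For list shifts against controllers, digit codes alone and the code form are 1 check, as is the omission of replicate 5 for viremic non-progressors. The platelet list in CD8 arrays has no value under the filter on detection in at least 0.5 of the arrays, which left no member. Causes were not tested unless one is named.

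The count for CD4 cells of rapid progressors against controllers (22) was 13 without background correction, 14 with normexp, 12 with the authors' values and 13 with the code form as a covariate, and 11 to 14 of the genes called in each case were among the 22. It was 2 in donors with codes of digits alone, both among the 22, where fewer donors were compared. Under the other alternatives it ranged within 1.5 times 22. The CD8 count (156, 123 higher) was 90 without a filter, 100 without background correction, 35 with cyclic loess (34 higher, 1 lower), 102 with the authors' values, 71 with array weights (63 and 8), 23 with the code form (21 and 2), 10 with digit codes alone (9 and 1), 36 with probes detected (34 and 2) and 308 with the monocyte mean (211 and 97), 117 of them among the 156. For CD4 cells of viremic non-progressors against controllers, the 2 genes became 5 with detection on at least 0.5 of the arrays, 8 with array weights, 6 with only the 2 groups, 0 with digit codes alone, and 1 without background correction, with normexp, loess, the authors' values, a trended prior, the code form, either covariate, and without any 1 viremic non-progressor (1 to 1). For viremic non-progressors against controllers, digit codes alone leave the same donors as the omission of replicate 5, with fewer rapid progressors in the fit. Without a filter, 1 gene was called for rapid progressors against viremic non-progressors in CD4 cells, lower in rapid progressors.

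For differences of a status effect between cell types, rapid progressors minus viremic non-progressors (1 gene) gave 0 without the donor block, without background correction and with the authors' values, 3 with digit codes alone, and 0 to 7 without 1 viremic non-progressor (0 without replicate 2 or 4, 7 without replicate 5). Rapid progressors minus controllers (1 gene) gave 0 without background correction, with the authors' values and with digit codes alone. Viremic non-progressors minus controllers (2 genes) gave 0 without the donor block, 1 without a filter, 4 with digit codes alone, and 0 to 4 without 1 viremic non-progressor (0 without replicate 2 or 4, 1 without replicate 3, 4 without replicate 5).

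The interferon list shift of rapid progressors and of viremic non-progressors against controllers in CD4 cells kept its direction and call in all 10 and all 15 alternatives of the permutation test, with adjusted p from 3.72e-04 to 0.0467 and from 0.0094 to 0.0467. In CD8 cells of rapid progressors it kept both in all 10, but camera with an estimated correlation gave 0.0649. In CD8 cells of viremic non-progressors it kept its direction and lost its call at 0.50 with detection on at least 0.5 of the arrays, 0.42 with digit codes alone and with the code form, 0.38 with probes detected, 0.42 to 0.56 without 1 viremic non-progressor (kept only without replicate 4), and 0.411 as the camera p with an estimated correlation. Rapid progressors minus viremic non-progressors ranged from -0.0741 to 0.0439 (positive without replicates 1 and 4) without 1 viremic non-progressor in CD4 cells, and in CD8 cells camera with the preset correlation gave 5.20e-11. Its difference between cell types for viremic non-progressors minus controllers ranged from -0.50 to -0.29 without 1 viremic non-progressor and kept its call only without replicate 5, and that for rapid progressors minus controllers, not called, was 0.0266 with digit codes alone. Within controllers the correlation of the list between cell types fell to 0.70 without the 2 farthest donors, and for that omission was 0.86 without background correction and 0.84 in the authors' values.

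The other 10 called list shifts kept their direction and stayed called in 81 of 139 alternatives, camera included. By permutation alone they stayed called as follows: antigen processing in 4 of 15, T cell activation in 5 of 10, regulatory T cell in 8 of 10, monocyte markers in 10 of 14, cell cycle in 7 of 10, 4 of 15 and 10 of 10, and restriction factors in 7 of 10, 11 of 15 and 8 of 10 (CD4 cells of rapid progressors and of viremic non-progressors, then CD8 cells of rapid progressors). The 28 called genes of the status comparisons stayed called in 406 of 532, with 0 reversed. Of 198 values for the 18 genes named between cell types, 177 kept their call, 20 lost it, and 1 was reversed: CD4 stood 0.31 higher in CD8 arrays in the authors' values, whose median was 7.26 in CD8 arrays against 6.51. With each cell type normalized on its own after the main background correction CD4 was not reversed, so separate normalization alone does not account for it. Signal over background limits genes near the floor: FSHR, at 5.38 in CD8 cells of rapid progressors, had a difference of -0.29 between cell types without background correction against -0.86 with it.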

Other observations

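The plasma cell list and the covariates in this part were chosen only after the data were seen.

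The cell cycle list was 0.5799 higher in CD8 cells of rapid progressors than of controllers, and genes of antibody-producing cells were higher beside it. JCHAIN and MZB1, chosen after their values were seen, were higher by 1.45 ± 0.37 and 1.07 ± 0.23 (limma adjusted p = 0.0322 and 0.00894), and a plasma cell list of 9 genes, 5 of them measured, was higher by 0.53 (exact p = 8.53e-04). Dividing plasma cells in the CD8 fraction were therefore a candidate source of the cell cycle signal. With the monocyte marker mean as a covariate the cell cycle shift was 0.6827 (exact p = 2.10e-05), and with the number of probes detected it was 0.5287 (exact p = 8.39e-04). These values argue against the amount of monocyte RNA and array quality as the whole cause. With the plasma cell mean as a covariate the shift was 0.5499 (exact p = 5.36e-04). That mean follows all plasma cell RNA through 5 genes, so it cannot decide whether dividing plasma cells were the source. Dividing plasma cells and dividing CD8 T cells both stay open, and the latter were not tested.

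Monocyte transcripts were abundant in the purified CD4 cells as well. The monocyte list averaged 10.1 ± 0.64 in controllers, 10.42 in viremic non-progressors and 10.56 ± 0.68 in rapid progressors, and CD14 stood at 12.21 ± 0.84 in rapid progressors. The second monocyte list differed between rapid progressors and controllers by 0.43 in CD4 cells (exact p = 0.0682) and by 0.67 in CD8 cells (exact p = 0.0250).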
